A study of Mus musculus with 2 samples.

How the data were processed

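Gene expression was measured by RNA sequencing in the cortex of mouse embryos at embryonic day 14.5, in 2 samples. One sample carried the deletion of Trrap, the scaffold protein of several histone acetyltransferase complexes, driven by Nestin-Cre in the developing nervous system (Trrap-deleted). The other was entered as wild type, and its description states that it was heterozygous for the floxed allele and also carried Nestin-Cre; it is called the control here. Per the labels' protocols, total RNA was extracted with a lipid tissue kit, and 2.5 µg went into each library, made with a TruSeq RNA kit. Whether the reads were counted by strand is not given in the sources used here, so reads of overlapping genes on opposite strands may not have been told apart. The labels do not say how many embryos contributed to each sample or what sex they were.

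The submitters' processing notes name TopHat2, without a version, and genome build mm9. The counting and testing software is not given in the sources used here. The single deposited file has the column layout and locus identifiers that Cuffdiff writes: each row holds a gene locus, a value for CONTROL, a value for KO, a log2 fold change, a test statistic, a p-value and a q-value. The 2 value columns were read as FPKM (fragments scaled for transcript length and library size) as deposited by the authors, a unit taken from that layout since the file does not write it. The log2 fold change as deposited by the authors equals log2 of KO over CONTROL to within 1.18e-05 in the rows with a value above 0 in both libraries. The p-value and the q-value of each row are the authors' deposited values from their own test. The 2381 rows are only those the authors marked significant, with a highest q-value of 0.0500 against their threshold of 0.05, so loci that did not pass and loci not expressed are absent alike. A gene missing from the table is therefore called not listed, and never unchanged. Per-library read totals are not given in the sources used here, FPKM values carry no counts, and the depth of both libraries is unknown, so no counting interval or detection limit could be set for a gene. No other column of per-sample values was present.

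With 1 library per genotype there was no replicate error and no test of significance of differences between genotypes could be run here; every listed difference rests on the authors' test, and whether that test used further libraries is not stated. Loci are given as the table lists them, on mm9, with the start moved to 1-based counting. The end minus the start in the file equalled the annotated gene length of GENCODE M21 for 447 of 2114 symbols and fell 1 base short of it for 30, which is how a start counted from 0 would look. A locus in the table can span several overlapping genes. GENCODE M21 and NCBI's gene table, which are on another build, were used only for gene types, by symbol; 2294 rows (96.3%) matched.

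Before the data were examined, 28 gene lists with 896 different symbols were fixed from textbook knowledge: cell-cycle phases, centrosome and microcephaly genes, cell-cycle exit, p53 targets, markers of cortical progenitors and neurons, synapse, markers of 9 other cell types or brain regions, complexes containing Trrap, Myc targets, stress response, hypoxia, immediate early genes, the respiratory chain, signalling, axon guidance, imprinted genes and sex-linked transcripts. Of these symbols 191 had a row of their own with values above 0 in both libraries. A symbol with more than 1 row (11 symbols) was represented by the row with the highest mean FPKM, and the 59 rows with several symbols were left out of lists. For each of the 23 lists with at least 3 listed genes, the median log2 fold change was set beside the medians of 10000 random lists of the same size, drawn from the same table and matched gene by gene on 10 equal bins of mean FPKM. A list was said to stand apart when its median lay within the lowest or highest 2.5% (250 random lists). The number of members lower in the Trrap-deleted library was compared with random lists in the same way, a measure added after the data were seen. These positions describe these libraries and are not p-values, since genes are not replicates. No allowance was made for the number of lists compared. The procedure was tested on simulated data: in a table of 2306 genes with random directions, 4.5% of 200 simulated lists of 15 genes stood apart by the median and 5% by the number of members lower; where members were lower with a chance of 90%, 47.5% and 92.5% did. The median alone was thus the less sensitive measure in this simulation. The simulated directions were drawn gene by gene without regard to expression level, so these rates need not hold for the real lists.

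Genes were named by a rule fixed in advance: Trrap; the 8 largest increases and 8 largest decreases among single-symbol rows with a value above 0 in both libraries and an FPKM of at least 5 in the higher one; from each list with at least 3 listed genes up to 4 members with the largest change and an FPKM of at least 1 in the higher library, and all listed members of smaller lists; and the 5 rows with the highest FPKM. Genes named outside that rule are said to have been chosen after their values were seen. A few genes that the rule names are not reported here. Alternatives fixed in advance were a q-value under 0.01, minimum differences of 1.5-fold and 2-fold, minimum FPKM of 1 and 5, leaving out rows with a 0, 1 row per symbol, rescaling of the libraries, pseudocounts of 1 and 0.1, and random lists not matched or matched also on locus length. Leaving out the sex chromosomes or pseudogenes was added later, as was the rescaling of lists and named genes, and 4 further gene lists were written after the first lists had been examined and before their own values were, except for symbols already in the first lists, of which Psrc1 alone was listed. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.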

Results

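The series compared gene transcription in Trrap-deleted embryonic mouse cortex with that of the control. The control was described as heterozygous for the floxed allele and also carried Nestin-Cre. The title of the series places the comparison in the question of how Trrap-dependent histone acetylation acts on the cell cycle and fate of neural progenitors. There were 2 samples of embryonic cortex, 1 per genotype, and the values are the FPKM of the loci that the authors called significantly different between them. Neither genotype had a replicate library here, so no value below has a standard deviation, and the spread between embryos is unknown. All fold changes are Trrap-deleted over control, and "listed" means that the locus passed the authors' test. The depth of the libraries is unknown. Trrap itself had no row in the table, so its transcript gave no check of the labels.

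More loci were listed higher than lower in the Trrap-deleted cortex. Of 2381 rows, 1382 (58.0%) were higher and 999 (42.0%) were lower in the Trrap-deleted cortex, with a median difference of 1.88-fold among the higher and 1.74-fold among the lower rows with values in both libraries. Among loci with an FPKM of at least 5 in the higher library, 954 were higher and 874 lower (52.2% higher). Under the same limit, and outside the Y chromosome and pseudogenes, the largest increases were in Gcg, the glucagon precursor gene (chromosome 2, 62312584 to 62321707), which went from 0.616 to 13.2 FPKM (21.5-fold), and Aldh1l1, a folate enzyme and astrocyte marker (chromosome 6, 90436421 to 90550197, 1.27 to 11.7 FPKM, 9.18-fold). Plekhb1 (0.950 to 7.68 FPKM, 8.09-fold) and Naaa (0.979 to 6.83 FPKM, 6.98-fold) came next under the same limit. Leaving aside pseudogenes and the uncertain row Gm6020, large decreases were in Bok, a Bcl-2 family member (chromosome 1, 95582271 to 95592339), which fell from 15.9 to 2.62 FPKM (6.08-fold lower), Pycr1, an enzyme of proline synthesis (11.5 to 2.06 FPKM), Rnf122 (12.5 to 2.29 FPKM) and 3110035E14Rik (15.5 to 2.86 FPKM). These loci passed the authors' test, which is not known to cover the spread between embryos, since 1 library per genotype is given.

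**Figure D1:**
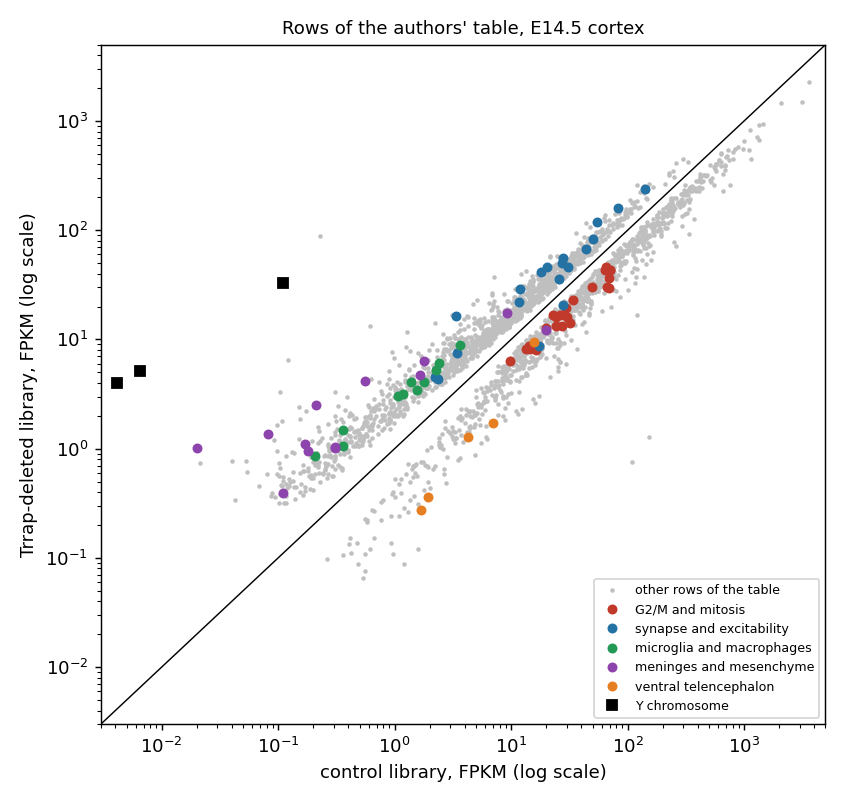
FPKM in the control library (x axis, log scale) against FPKM in the Trrap-deleted library (y axis, log scale) for the rows of the authors' table with values above 0 in both, with members of 5 gene lists and the Y-linked rows coloured and the diagonal marking equal values. All 23 listed genes of the mitotic list lie below the diagonal, 17 of 19 synaptic genes lie above it (16 after rescaling to a median log2 fold change of 0), and the 3 Y-linked rows lie far to the left.

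Genes of the fixed mitotic list were lower in the Trrap-deleted cortex. Of 65 symbols in the list of G2/M and mitosis genes, 23 were listed and all 23 were lower, with a median log2 fold change of -0.71 (1.64-fold lower) and a range from -1.25 to -0.44. The largest differences were in Cdca3, a trigger of mitotic entry (chromosome 6, 124779527 to 124783825, 69.7 to 29.4 FPKM), and Pttg1, the securin that holds back sister chromatid separation (32.2 to 14.1 FPKM). Ube2c, the E2 enzyme of the anaphase-promoting complex (66.2 to 30.2 FPKM), and Ccnf, cyclin F (16.4 to 7.94 FPKM), came next. Chosen after their values were seen, Ccnb1 (cyclin B1) went from 64.2 to 42.9 FPKM and Cdc20 from 69.7 to 36.5. Likewise chosen afterwards, Plk1 went from 20.0 to 12.8 FPKM and the proliferation marker Mki67 from 70.2 to 43.1. Ccna2 shares a row with another gene and was not counted. Only 36 of 10000 random lists matched on expression level had a median as low, and 0 of 10000 had 23 members lower, against a mean of 10.5. Y-linked transcripts, microglial markers (11 of 11 listed) and meningeal markers (12 of 13) were higher in the same library, and ventral telencephalic markers (5 of 5) were lower.

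Other cell-cycle lists had fewer listed members. Of 50 genes of G1/S and DNA replication, 5 were listed and 4 of them were lower. Rrm2, a ribonucleotide reductase subunit (63.9 to 29.8 FPKM), Cdk4, the cyclin D kinase (691 to 353 FPKM), and Cdc25a, a phosphatase that activates cyclin-dependent kinases (13.1 to 7.39 FPKM), were lower, as was Dbf4, named after its value was seen. Ccnd3, cyclin D3, was higher (11.8 to 19.3 FPKM). This list did not stand apart from random lists (409 of 10000 as low), and the 45 other symbols, which include the replicative helicase genes, were not listed. The 4 listed genes of 24 in the list of microcephaly and centrosome genes were all lower: Cenpj (8.85 to 4.71 FPKM), Nde1 (45.9 to 26.3 FPKM), Cep55 (14.8 to 9.73 FPKM) and Nin (13.3 to 9.92 FPKM), with 1031 of 10000 random lists as low in the median. Among inhibitors of the cell cycle and exit genes, Cdkn1c, which encodes the CDK inhibitor p57, was 4.91-fold lower (29.5 to 6.002 FPKM), and Ccng2 was 2.18-fold lower (65.2 to 29.97 FPKM). Btg1 fell from 23.2 to 18.2 FPKM and Ccng1 was 1.77-fold higher (11.7 to 20.6 FPKM). The 6 listed p53 targets split into 4 higher, among them Sesn2 (1.505 to 3.25 FPKM), and 2 lower, Psrc1 (29.7 to 10.9 FPKM) and Trp53inp1 (41.6 to 18.5 FPKM), so the list had no common direction.

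Genes of nucleolar function and Myc targets were lower in 7 of 7 listed cases (median log2 fold change -0.72). Hk2, a hexokinase, went from 9.46 to 3.16 FPKM, Dkc1, which encodes dyskerin, from 63.5 to 34.3, Nop58 from 38.6 to 21.3 and Odc1, the first enzyme of polyamine synthesis, from 141 to 86.0. By the median this list lay within the random range (697 of 10000 as low). By the number of members lower it stood apart (154 of 10000 with 7 lower). Its genes are abundant, and abundant loci were mostly listed lower. Of 10 equal groups of rows by mean FPKM, the most abundant had 17.3% of rows higher and the least abundant 81.5%. The random lists were matched on bins of mean FPKM and so carry this trend, with a mean of 4.12 of 7 members lower. The 5 rows with the highest FPKM were all lower: CT009594.1 (3636 to 2266 FPKM), the alpha-tubulin gene Tuba1a (3115 to 1491), the ribosomal protein gene Rps15a (2077 to 1472), the actin gene Actg1 (1462 to 939) and Ptma (1353 to 675). CT009594.1 has a very short locus (chromosome 17, 21421067 to 21421176) and no annotated type, so its value is uncertain.

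**Figure D2:**
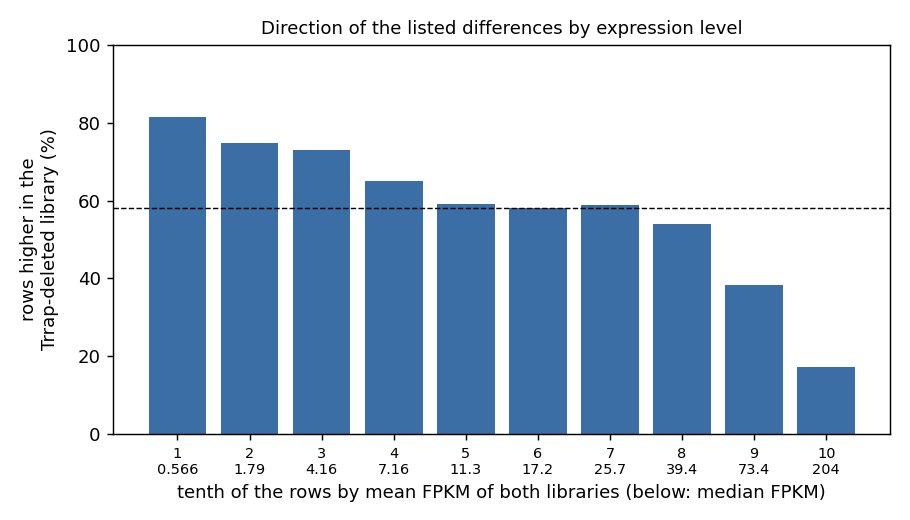
Percent of rows listed higher in the Trrap-deleted library (y axis) for 10 equal groups of rows ordered by mean FPKM of both libraries (x axis, with the median FPKM of each group below). The bars go from 81.5% in the lowest group to 17.3% in the highest; the dashed line marks the share over the rows with values above 0 in both libraries.

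Progenitor markers moved both ways. Of the 9 listed genes of apical progenitors and radial glia, 5 were lower and 4 were higher, or 3 higher if the libraries were rescaled so that the median of the listed rows was 0. The apical membrane marker Prom1 (24.9 to 8.32 FPKM), the Notch effector Hey2 (4.48 to 1.60 FPKM) and the matrix gene Tnc (9.25 to 4.45 FPKM) were lower, and the glutamate transporter gene Slc1a3 was higher (30.7 to 55.1 FPKM). Prom1 has a second, weaker row at the same locus that was also lower (2.67 to 0.654 FPKM). Pax6 and Sox2 were not listed. Of 7 listed genes of basal progenitors and neurogenic commitment, 5 were higher as deposited and 3 after that rescaling, among them Mfap4 (69.0 to 124 FPKM), Jag2, a Notch ligand (2.73 to 5.49 FPKM), and Sox4 (127 to 225 FPKM), which shares its locus with another row and is uncertain, and Nhlh2 was lower (12.3 to 6.41 FPKM). The median of this list was 0.46 as deposited and -0.09 after the rescaling. Neither list stood apart from random lists (2171 of 10000 as low and 1339 of 10000 as high).

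Synaptic genes were higher in the Trrap-deleted cortex. Of 54 symbols, 19 were listed, 17 higher (16 after the rescaling to a median of 0) and 2 lower, with a median log2 fold change of 0.92 (1.90-fold). Camk2a, a kinase of the postsynaptic density (chromosome 18, 61085260 to 61147813), went from 3.34 to 16.2 FPKM (4.86-fold). Slc17a7, the vesicular glutamate transporter VGLUT1, went from 20.2 to 46.5 FPKM and the vesicle protein gene Sv2a from 18.0 to 41.2. Syn2, synapsin II, went from 11.8 to 28.8 FPKM, with a second row at the same locus that was also higher. The 2 exceptions, Rab3c (17.2 to 8.76 FPKM) and Slc17a6, the vesicular glutamate transporter VGLUT2 (28.1 to 20.6 FPKM), were named after their values were seen. None of 10000 random lists had a median as high, and 1 of 10000 had so few members lower. The same microglial, meningeal and Y-linked differences accompany this list. General markers of postmitotic projection neurons did not move with them: 7 of 16 listed were higher (5 after the rescaling) and 9 lower. Thy1 (1.45 to 4.67 FPKM), Scg2 (1.27 to 3.76 FPKM) and Syt4 (17.0 to 39.6 FPKM) were higher and Stmn2, a microtubule regulator of growing axons, was lower (158 to 53.9 FPKM). Of random lists, 3780 of 10000 had a median as low. Of 14 listed axon guidance and adhesion genes 10 were higher (8 after the rescaling to a median of 0, 11 after one by summed FPKM), a split within the random range. Cntn1 (2.82 to 10.1 FPKM), Cdh8 (15.4 to 35.2 FPKM) and Plxna4 (21.9 to 45.3 FPKM) were higher and Efna2 was lower (8.52 to 3.89 FPKM).

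**Figure D3:**
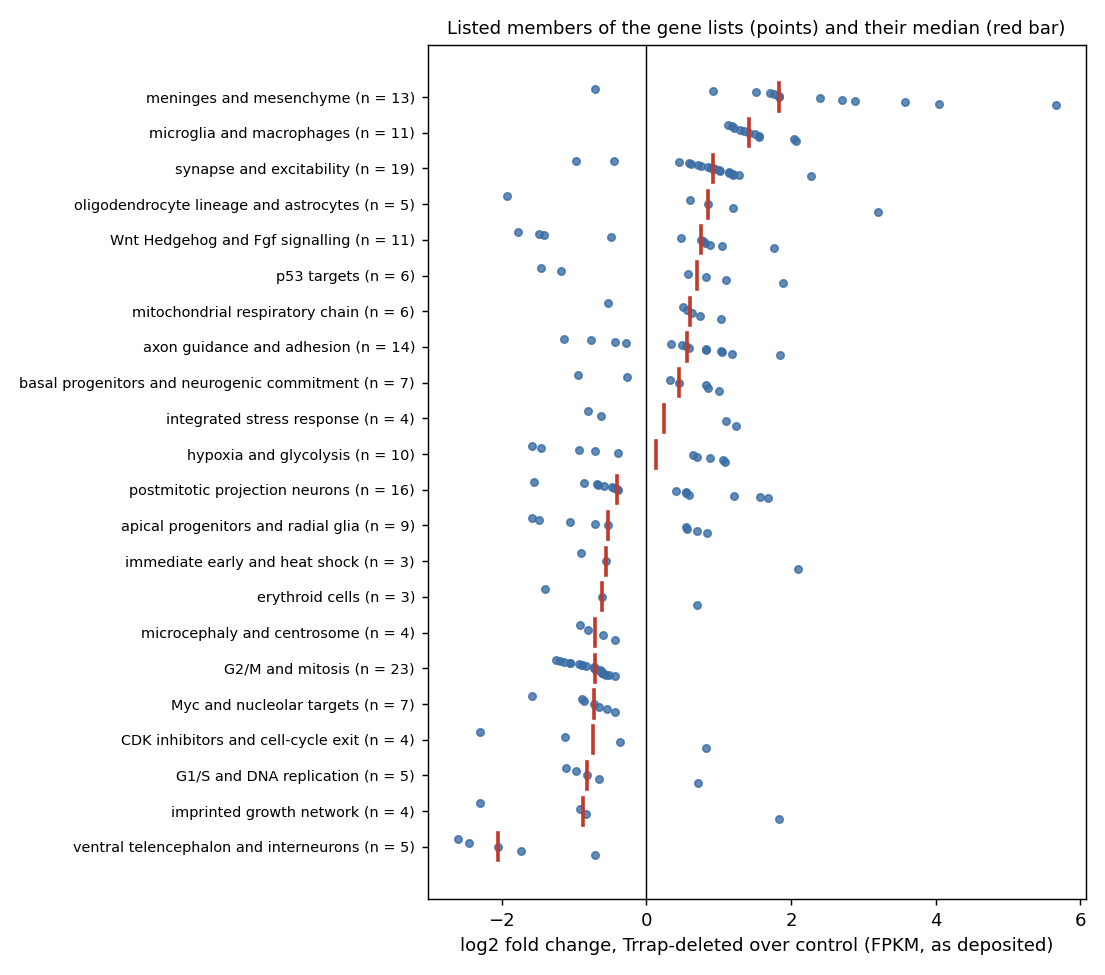
log2 fold change of FPKM, Trrap-deleted over control (x axis), of each listed gene (points) for the fixed lists with at least 3 listed genes (y axis), ordered by median (red bar); the sex-linked list is left out because its folds exceed the axis. The G2/M list lies wholly below 0 with a median of -0.71, the synaptic list has a median of 0.92, and the ventral telencephalic list has the lowest median, -2.04.

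Listed genes of the ventral telencephalon, where cortical interneurons are born, were lower in the fixed list. All 5 listed genes of 32 went down, with a median of 4.13-fold, among them the homeobox genes Dlx5 (1.68 to 0.276 FPKM), Dlx2 (1.95 to 0.358 FPKM) and Lhx6 (chromosome 2, 35937407 to 35960928, 7.06 to 1.71 FPKM). Of random lists, 4 of 10000 had a median as low. In a second list of ventral telencephalic genes, described further below, 4 of 6 listed members were lower and 2 higher. Lhx9, the only listed gene of the diencephalon and other brain regions, was also lower (13.7 to 4.72 FPKM).

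Listed microglial and most listed meningeal markers were higher, mostly at low absolute levels. All 11 listed microglial and macrophage genes of 28 were higher, with a median of 2.67-fold: the complement genes C1qa (1.07 to 3.02 FPKM) and C1qc (1.38 to 4.07 FPKM), Lyz2 (0.359 to 1.06 FPKM) and Fcgr3 (0.357 to 1.49 FPKM). Of 13 listed meningeal and mesenchymal genes 12 were higher, with a median of 3.57-fold: the collagen genes Col1a1 (0.0825 to 1.37 FPKM), Col1a2 (0.210 to 2.50 FPKM) and Col3a1 (0.558 to 4.13 FPKM) and Lum (0.0203 to 1.02 FPKM), while Fn1, the exception, named after its value was seen, was lower (19.9 to 12.2 FPKM). Loci this weak were listed only with large differences, and most of them were listed higher. The microglial median lay within the random range (1319 of 10000 as high) and the meningeal median stood apart (50 of 10000 as high), while by the number of members lower the meningeal list did not (1347 of 10000 with as few). Ttr, the only listed choroid plexus gene, went from 0.104 to 3.31 FPKM, at a locus in the table far longer than the annotated gene, so its value is uncertain. Of 30 endothelial and pericyte genes, Pdgfrb (1.71 to 3.60 FPKM) and Cspg4 (0.353 to 0.635 FPKM) were listed, both higher. The 3 listed erythroid genes did not share a direction: embryonic globin Hbb-y was higher (96.8 to 157 FPKM), and the transferrin receptor gene Tfrc (24.3 to 9.24 FPKM) and Add2 (33.0 to 21.6 FPKM) were lower. Of 5 listed genes of oligodendrocytes and astrocytes 4 were higher, among them Clu (15.01 to 34.6 FPKM) and Sparcl1 (9.55 to 14.6 FPKM). Cspg4, given above with the pericyte genes, is also 1 of these 4. The remaining gene was lower (log2 fold change -1.93), and only 3 of the 5 reached an FPKM of 1 in the higher library.

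The libraries also differed in sex-linked transcripts, 3 of 4 listed being higher in the Trrap-deleted library. The Y-linked genes Eif2s3y (0.111 to 32.8 FPKM), Ddx3y (0.00653 to 5.18 FPKM) and Kdm5d (0.00414 to 3.99 FPKM) were near 0 in the control library and present in the Trrap-deleted library, and Xist, the RNA that coats the inactive X chromosome, went from 313 to 142 FPKM. These transcripts differed together with every group described above, since each genotype had 1 library.

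The remaining lists did not stand apart from random lists by the median. Of 11 listed Wnt, Hedgehog and Fgf signalling genes 7 were higher (6 after the rescaling to a median of 0), among them Gli1, a Hedgehog effector (0.578 to 1.97 FPKM), and Sfrp1, a Wnt modulator (63.1 to 130 FPKM), and Wnt8b (4.38 to 1.57 FPKM) and Rspo2 (3.22 to 1.21 FPKM) were lower. Of 6 listed respiratory chain genes 5 were higher (4 after that rescaling), with Ndufs8 at 22.7 and 46.6 FPKM, Ndufb3 at 33.2 and 55.7, Ndufa1 at 66.6 and 103, and Uqcr11 at 64.7 and 95.8 in control and Trrap-deleted cortex (376 of 10000 random lists as high). The 10 listed hypoxia and glycolysis genes split into 5 higher and 5 lower, with a median of 0.13 as deposited and -0.41 after that rescaling: Egln3 (4.12 to 8.81 FPKM) and Hk1 (17.6 to 36.8 FPKM) were higher, while Pfkfb3 (16.1 to 5.88 FPKM) and Hk2 were lower. The integrated stress response list split into 2 higher and 2 lower, with a median of 0.24 that became -0.30 under that rescaling, and with the transcription factor gene Atf4 (74.7 to 42.7 FPKM) and Gars (57.9 to 37.5 FPKM) lower and Chac1 (0.572 to 1.35 FPKM) and Sesn2 higher. Imprinted genes other than Cdkn1c and Dcn (1.79 to 6.34 FPKM) were represented by Grb10 (93.3 to 49.7 FPKM) and Nnat (803 to 452 FPKM), both lower. Dcn, which was higher, also belongs to the meningeal list. H19 shares a row with another gene and was not counted. Dusp1 (11.9 to 6.39 FPKM) and the heat shock gene Hsph1 (76.9 to 52.5 FPKM) were lower among 3 listed immediate early and stress genes, and 1 was higher (log2 fold change 2.10). Of 39 subunits of complexes containing Trrap, only Atxn7 was listed, at 9.03 FPKM in the control and 12.4 in the Trrap-deleted cortex, a log2 fold change of 0.46 that became -0.09 under the rescaling to a median of 0. Nhlh2 was the only listed gene of the Cajal-Retzius list.

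The authors' deposited table also lists differences in loci that may not be unique in the genome. Gm13509 (0.229 to 88.7 FPKM) and Gm8055 (0.122 to 6.55 FPKM) were among the largest increases, and Gm15710 (154 to 1.27 FPKM) and Gm13577 (120 to 16.8 FPKM) among the largest decreases. These 4 are annotated as processed pseudogenes, whose reads can be split with their parent genes, and their values are uncertain; so are those of Gm6020 (109 to 0.762 FPKM). The loci of Gm6020, Gm15710, Gm13509 and Gm8055 in the table are far longer than the genes annotated under those symbols. Over the table, 190 rows were annotated as pseudogenes, 165 of them lower and 25 higher, while 1282 of 2036 protein-coding rows (63.0%) were higher. In the control library 4 rows were listed at 0 and 1 was in the Trrap-deleted library; no fold was given for these.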

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

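Chosen after the data had been seen were the settings without the sex chromosomes or without pseudogenes, the number of members lower, and the rescaling of lists and named genes. Counts of loci moved by more than 1.5 times only at stricter thresholds. At a q-value under 0.01, 906 loci were higher and 647 lower. At a difference of at least 2-fold, 606 were higher and 325 lower, with the rows at 0 in either library included. The share higher, 58.0% with an exact 95% interval of 56.0% to 60.0% that covers counting only, became 65.1% at 2-fold or more, 52.2% at an FPKM of at least 5, 62.7% without pseudogenes and loci of unknown type, and 50.1% after rescaling to a median log2 fold change of 0, which sets the share near 50% by construction. That rescaling subtracts 0.54 from every log2 fold change, which lowers it, and that by summed FPKM subtracts -0.35, which raises it; since the table holds only called loci, neither is a normalization over all genes. By the number of members lower, 1 list stood apart on the higher side in place of 3 by the median, since the meningeal and sex-linked lists no longer did; on the lower side 3 did in place of 2, with the Myc list added. The median of the microglial list stood apart at log2(FPKM + 1) (0.93) and against unmatched random lists (1.42), and that of the glial list at an FPKM of at least 1 (1.20, from 3 genes). Medians changed sign for projection neurons at a q-value under 0.01 (0.051); for the stress response at log2(FPKM + 1) (-0.016), at a q-value under 0.01 (-0.63) and under the rescaling to a median of 0 (-0.30); and under that rescaling for basal progenitors (-0.087), hypoxia and glycolysis (-0.41) and the gene Atxn7 (-0.087). The other 170 list medians and 427 gene values under alternatives kept their direction. The causes were not tested. Trrap was not listed and had no value under any setting, and lists left with fewer than 3 members under a setting got none. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out. Depth is unknown: weak loci were listed higher only from 0.83 on the log2 scale in the least abundant of 10 equal groups, against 0.30 in the most abundant.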

Other observations

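Chosen after the values they use had been seen were the comparison of symbol families and the tests of an effect on Xist alone, of a lower share of neural cells and of a lower share of cycling progenitors; the other tests were written down beforehand. The genes named here as members of families or added lists were chosen after their values were seen. Among 13 symbol families with at least 8 listed genes, ribosomal protein genes were lower in 34 of 35 cases (median log2 fold change -0.57; 32 lower after rescaling by summed FPKM), among them Rpl10 (291 to 135 FPKM) and Rplp0 (680 to 391 FPKM), with Rpl35 the exception as deposited (64.2 to 137 FPKM). Of random lists matched on bins of mean FPKM, 55 of 10000 had as many lower. The bin of the most abundant rows spanned 113 to 2951 FPKM, so the match on level was coarse there. Random lists for the families were not matched on locus length. Among equal groups of rows by locus length, the shortest (median 1055 bases) had 23.1% of rows higher, against 55.3% to 68.9% in the others. Whether locus length accounts for the lower ribosomal protein genes was not tested. Many ribosomal protein genes have near-identical pseudogenes, so their values are less certain than those of the other families. Zinc finger genes named Zfp were lower in 28 of 31 cases (median -0.76), and in 28 after the rescaling by summed FPKM, including Zfp57, which guards imprints (140 to 37.0 FPKM), Zfp266 (48.5 to 22.4 FPKM) and Zfp184 (15.9 to 6.24 FPKM). Zfp385a, Zfp511 and Zfp641 were higher, and 0 of 10000 random lists had as many lower.

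ATPase genes named Atp were higher in 15 of 16 cases (median 0.76; 14 higher after rescaling to a median of 0), and 4 of 10000 random lists had so few lower. They include subunits of the vesicular proton pump, Atp6v0c (85.1 to 151 FPKM) and Atp6v1a (30.3 to 48.6 FPKM), and the calcium pump gene Atp2b2 (10.7 to 23.9 FPKM). Genes named Tmem were higher in 33 of 41 cases (31 after rescaling to a median of 0), and 145 of 10000 random lists had so few lower. No allowance was made for the 13 families compared, so a position like that of Tmem may arise by chance. The 9 other families (Col, Fam, Gpr, Kcn, Kif, Rab, Rnf, Slc and Trim) lay within the random range by this measure.

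The first pattern is the presence of Y-linked RNA in the Trrap-deleted library alone, with Xist lower by 2.21-fold. An effect of the deletion on Xist alone would leave out the Y-linked genes, 3 of which differed by over 10-fold; they are part of the pattern itself and no separate test of it. A different sex makeup of the embryos in the 2 libraries predicts Y-linked RNA near 0 in only 1 library, which was seen. It also predicts that X-linked genes known to escape inactivation are lower where Y-linked RNA is present. Of the 4 listed escapees 3 were lower (Uba1, Ddx3x and Eif2s3x, with Car5b higher), which reached the share set beforehand. However, 5007 of 10000 random lists had as many lower, so the 4 escapees cannot decide. That explanation rests on the Y-linked RNA, which is part of the pattern itself. Xist remained at 45.3% of its control level, and the number and sex of the embryos are not given. Of 106 X-linked rows 42.5% were higher (exact 95% interval 32.9% to 52.4%), against 58.9% of autosomal rows (56.8% to 60.9%). Both intervals cover counting only, since genes are not replicates. X-linked and autosomal rows were not matched on expression level, locus length or pseudogene content, so the gap cannot be assigned to sex. Without the sex chromosomes 58.7% of rows were higher.

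The second pattern is that microglial and meningeal markers were higher and ventral telencephalic markers lower. Technical candidates are the cut of the dissection and meninges left on the tissue. Of a second list of meningeal fibroblast genes 71.4% of 7 listed members were higher, within the random range (1217 of 10000 with a median as high, 5154 with as few lower), and of a second list of ventral telencephalic genes 66.7% of 6 listed members were lower (Dlx6as1, Prox1, Nxph1 and Cxcr4), with a median that 65 of 10000 random lists reached and a number lower that 424 reached; both shares fall between the bounds set for and against, so more meningeal tissue and less ventral tissue or fewer ventrally born cells remain open. A lower share of neural cells would raise the other cell types alike; the lower quartile of the meningeal list lay 0.15 above the upper quartile of the microglial list on the log2 scale, but only 4 listed meningeal genes had a control FPKM of at least 1, and weak genes are listed only with large differences, so that too cannot be told apart from the rest. A biological loss of interneurons or gain of microglia after Trrap deletion was not tested and stays open.

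The third pattern is the lower level of the mitotic list. Bias by locus length and expression level as the whole cause is argued against by random lists matched on both. Of these lists 0.37% had a median as low. Transcript length was not matched, so bias by it was not tested. A second cell-cycle list, written after the first had been seen, had 26 of 28 listed members lower (median -0.75). It was led by Stmn1 (762 to 258 FPKM), Psrc1, already seen as a p53 target, and Depdc1b (8.12 to 3.29 FPKM), with Cenpm and Cenpn higher. Read in the same 2 libraries, the second list is no independent support for the first. A lower share of cycling progenitors could account for the lower mitotic level as well as lower transcription per cell. Of the 9 listed apical progenitor markers 55.6% were lower, which decides neither way. Sex-linked, microglial, meningeal and ventral telencephalic markers differed between the same 2 libraries. Other differences between the 2 samples therefore cannot be told apart from either cause. An effect of Trrap deletion on transcription of the mitotic genes was not tested apart from these and stays open.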
